A study of Mus musculus with 12 samples.

How the data were processed

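Total RNA of mouse heart, depleted of ribosomal RNA, was sequenced in 12 libraries of 3 groups with 4 mice each. Groups were taken from the labels, and the numbers that name the mice are not shared between groups, so no pairing was used. The deposited files hold 1 value per transcript and library. Their unit is not named in the headers and was read from the values as FPKM, fragments scaled by transcript length and by library size, as made by the authors: the value multiplied by the annotated transcript length was a whole multiple of 1 constant per library, within 0.1 of a whole number, for 98.5% to 98.8% of the values tested. The constant gives the number of fragments behind each library. The labels name the build mm10 and the tool limma without a role, and the aligner and quantifier are not given in the sources used here. The 8 Control and LPS files list the same 36293 transcripts and the 4 LPS+XJDHT files another set of 35802, of which 33137 are in both. In either set a transcript is listed when the mean of at least 1 of the groups it was made for is about 0.5 FPKM or more. Transcripts assembled by the authors without an Ensembl identifier were left out of the comparisons, as were 37 Ensembl transcripts that the annotation used here, GENCODE for GRCm38, does not hold.

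Gene expression was the sum of FPKM over the 24723 annotated transcripts in both sets, which gave 12866 genes. Values were log2-transformed after adding a pseudocount of 1, and genes with at least 1 FPKM in at least 4 libraries were tested, 11509 in all. A single linear model with 1 mean per group and no covariate was fitted with limma 3.58.1 (empirical Bayes with an intensity trend) in R 4.3.3, and the 3 groups were compared in pairs, two-sided, with Benjamini-Hochberg adjusted p below 0.05. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. For single values per library an exact permutation test over all splits was used.

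Before the data were examined, 49 gene lists were fixed (28 of pathways, 19 of cell types and 2 for checks), as were the rule for named genes and the alternatives. The 38 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over lists within a comparison. Named genes are those past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, without predicted genes and clones: the 10 with the largest change each way, or 5 each way for LPS+XJDHT against Control. Where 0 genes met the rule, the 5 with the smallest p were taken. To these come up to 4 members of each list with the smallest adjusted p and a fixed panel of inflammatory, stress and metabolic genes. The rule was written for counts and was applied to FPKM. A small intestine and a testis list were added after the data were seen, from textbook markers.

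Alternatives were no filter, a limit of 5 FPKM, pseudocounts of 0.1 and 0.5, a fit of the compared groups alone, a minimum of 2-fold, removal of mitochondrial and haemoglobin genes or of abundant small RNAs, and leaving out each library. Added after the data were seen were median-ratio scaling, limma-voom on recovered fragments, sample quality weights, all transcripts of the Control and LPS files, and removal of the small intestine and testis genes. Alternatives planned for counts (relative log expression factors, DESeq2, and voom on counts) were not run, since the files hold no counts. The fit was tested on simulated data with independent normal noise for each gene, in which 200 genes were changed in each comparison. The changed genes were drawn from those with a mean of at least 2 on the log2(FPKM + 1) scale. Between 88 and 93 of 100 genes changed by 2 on the log2 scale and 69 of 100 changed by 1 were recovered, with 3 to 10 false calls. These rates do not cover genes nearer the limit of 1 FPKM or noise shared between genes. No columns of values were left unused. Some genes were not analysed here.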

Results

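RNA from the hearts of C57BL/6 mice was sequenced in 12 libraries, 4 in each of 3 groups. Control mice received saline, LPS mice received lipopolysaccharide at 10 mg/kg, and LPS+XJDHT mice received the same LPS dose together with XJDHT at 50 mg/kg per day, all over 3 days. Lipopolysaccharide is a component of the outer membrane of Gram-negative bacteria that activates innate immunity, and XJDHT is Xijiao Dihuang decoction, a traditional Chinese herbal formula. The libraries held between 73.8 and 77.8 M fragments (M, mega), a number recovered from the spacing of the values, with means of 76.4 ± 1.35 M in Control, 75.9 ± 1.49 M in LPS and 75.9 ± 1.68 M in LPS+XJDHT (SD, n = 4). Of the 12866 genes listed for all 12 libraries, 11509 reached 1 FPKM in at least 4 libraries and were tested. On the leading component of these genes, which held 46.4% of the variance, the 4 Control libraries lay between -54.0 and -49.1 and the other 8 between 13.1 and 35.6. In what follows, expression is the mean FPKM ± SD (n = 4 libraries per group), log2 fold changes come from limma on log2(FPKM + 1) with their SE where given, and positions are in the mouse genome build mm10.

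The comparison of LPS with Control asks what endotoxin does to transcription in the heart. Acute-phase and antibacterial genes reached some of the highest levels in the tissue after LPS. Saa3, a serum amyloid A of the acute-phase response, was 2681 ± 525 FPKM after LPS against 3.17 ± 0.544 FPKM in Control (log2 fold change 9.32 ± 0.19, adjusted p = 9.2e-11). Lcn2, the siderophore-binding lipocalin, was 2425 ± 528 against 7.39 ± 3.64 FPKM (log2 fold change 8.23 ± 0.26, adjusted p = 3.4e-09). At the same time part of the genes of contraction, ion channels and mitochondrial energy supply fell, among them Actc1, cardiac alpha-actin, at 962 ± 364 against 4711 ± 537 FPKM (log2 fold change -2.40 ± 0.36, adjusted p = 0.00038). In all, 3063 genes rose and 1384 fell, of which 865 and 393 changed at least 2-fold.

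Among the genes chosen by size of change, the other increases were of Serpina3n, a serine protease inhibitor, at 619 ± 129 against 9.47 ± 2.82 FPKM (log2 fold change 5.90), and of Cfb, complement factor B, at 114 ± 14.2 against 1.48 ± 0.484 FPKM (log2 fold change 5.55). Cxcl13, a chemoattractant of B cells, was between 18.9 and 71.0 FPKM in the LPS libraries and listed at 0 in every Control library. Cxcl5 and Cxcl1, which attract neutrophils, rose with log2 fold changes of 5.14 and 4.48. S100a8, a subunit of calprotectin, rose from 0.517 ± 0.327 to 38.7 ± 7.09 FPKM. Iigp1, an interferon-inducible GTPase, and Ptx3, a long pentraxin, had log2 fold changes of 4.64 and 4.49. The decreases were led by Cytl1, a secreted cytokine-like protein, at 1.70 ± 1.41 against 22.5 ± 5.99 FPKM (log2 fold change -3.21), and by Ppp1r3c, which targets protein phosphatase 1 to glycogen, at 5.56 ± 2.78 against 51.2 ± 6.34 FPKM (log2 fold change -3.07). Efnb3, an ephrin, fell by 2.89 on the log2 scale, Lsmem2 by 2.68, Ttll1, of the tubulin tyrosine ligase-like family, by 2.61 and C1qtnf9, a secreted C1q-related protein, by 2.56. The class II antigen-presentation genes H2-Aa and H2-Eb1 fell by 2.75 and 2.73. Carnmt1, a methyltransferase of carnosine, was listed at 0 in every LPS library and at 9.45, 10.5, 9.09 and 0.111 FPKM in the Control libraries (adjusted p = 0.011, and 0.15 by limma-voom). Immp1l, a subunit of the mitochondrial inner membrane peptidase, was between 25.0 and 37.2 FPKM in Control and at 17.3, 0.628, 0.433 and 2.73 FPKM in the LPS libraries (adjusted p = 0.030). That call was lost without any of the 4 Control libraries, without LPS 2, 3 or 4, with a pseudocount of 0.1 and by limma-voom, with adjusted p up to 0.14.

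Several immune gene lists rose by camera at its preset correlation, while others were split or short of the threshold. Of 21 acute-phase and antibacterial genes 18 rose and 0 fell, with a median log2 fold change of 3.44 (camera adjusted p = 1.7e-12, and adjusted p = 0.069 with an estimated correlation). Of 23 inflammatory cytokines and chemokines 18 rose and 1, Cxcl12, fell (camera adjusted p = 7.7e-07, and adjusted p = 0.069 with an estimated correlation). Ccl2, which attracts monocytes, reached 60.6 ± 17.4 against 2.73 ± 1.21 FPKM, and Ccl5 reached 14.0 ± 4.85 against 0.299 ± 0.491 FPKM. All 7 measured neutrophil markers rose, including S100a9 with a log2 fold change of 4.41 and Ngp at 11.2 ± 1.75 against 0.0782 ± 0.0788 FPKM (camera adjusted p = 2.3e-07, and adjusted p = 0.069 with an estimated correlation). Of 8 monocyte markers 4 rose, among them Chil3 with a log2 fold change of 3.31 and Plac8 with 3.35 (camera adjusted p = 0.015, and adjusted p = 0.15 with an estimated correlation). Of 33 interferon-stimulated genes 24 rose, and 26 when adjusted over the list alone, including the transcription factor Irf7 (38.6 ± 4.61 against 2.42 ± 0.840 FPKM), Ifit3 and Bst2 (camera adjusted p = 1.2e-08, and adjusted p = 0.13 with an estimated correlation). In the TLR4 and NF-kB signalling list 16 of 30 genes rose, among them the feedback inhibitors Tnfaip3 (log2 fold change 2.78) and Nfkbia (1.70) and the adaptor Myd88 (1.53), with camera adjusted p = 0.0020, and adjusted p = 0.16 with an estimated correlation. Of 18 complement genes 7 rose, including C3 at 219 ± 45.5 against 35.5 ± 6.12 FPKM (camera adjusted p = 0.033, and adjusted p = 0.58 with an estimated correlation), a call lost without Control replicate 3 or LPS replicate 3 or 4 (adjusted p up to 0.12). The antigen presentation list did not pass (camera adjusted p = 0.14), and 14 of its 20 members rose, such as the class I genes B2m and H2-D1 (log2 fold changes 2.30 and 2.20), and 6 fell, such as H2-Aa and H2-Eb1. Genes of the H2 family share sequence, so reads cannot always be assigned to 1 member. The endothelial activation and coagulation list did not pass by camera. Its adhesion genes Selp, Sele and Icam1 rose with log2 fold changes of 4.25, 3.20 and 3.17, while the apelin receptor gene Aplnr fell by 1.95. Apln, Angpt1 and Thbd fell too, and other members such as Kdr, Tie1 and Cdh5 did not pass (limma adjusted p = 0.93, 0.61 and 0.35).

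Part of the genes of tissue remodelling and defence against oxidants, and most of those of cytosolic ribosomes, rose as well. Of 38 extracellular matrix and remodelling genes 19 rose and 4 fell, or 5 fell when adjusted over the list alone (camera adjusted p = 0.043, and adjusted p = 0.45 with an estimated correlation). That call was lost without Control replicate 3, LPS replicate 3 or LPS+XJDHT replicate 2 (adjusted p up to 0.068). Timp1, an inhibitor of metalloproteinases, was 143 ± 40.5 against 6.68 ± 2.96 FPKM, Mmp3, stromelysin, was 102 ± 15.7 against 5.09 ± 1.72 FPKM and Lox, which cross-links collagen, was 39.0 ± 6.50 against 2.68 ± 0.684 FPKM. Of 29 genes of the antioxidant and metallothionein list 16 rose, or 17 with 1 falling when adjusted over the list alone (camera adjusted p = 0.00033, and adjusted p = 0.13 with an estimated correlation). Among the 16 was Cybb, which makes oxidants and is not a defence gene (log2 fold change 1.43). Mt1 was 1016 ± 130.2 against 239 ± 17.9 FPKM, and Fth1, the heavy chain of the iron store ferritin, was 2097 ± 286 against 939 ± 22.8 FPKM. Of 14 enzymes of nitric oxide, polyamine and prostanoid synthesis 9 rose, including Arg1 and Ptgs2 with log2 fold changes of 3.08 and 0.98 (camera adjusted p = 0.043, and adjusted p = 0.13 with an estimated correlation), a call lost without Control or LPS replicate 4 (adjusted p up to 0.078). Of 35 cytosolic ribosomal protein genes 32 rose, with a median log2 fold change of 0.69 and Rpl3 and Rps6 at 1.61 and 0.92 (camera adjusted p = 1.9e-13, and adjusted p = 0.13 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, which can take or give reads.

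Part of the genes of the working heart muscle fell, and some rose. Of 52 nuclear-encoded genes of the respiratory chain 37 fell and 0 rose, and 44 fell when adjusted over the list alone (camera adjusted p = 5.8e-17, and adjusted p = 0.12 with an estimated correlation). Their median log2 fold change was -0.34, and Ndufb10 of complex I was 187 ± 19.2 against 314 ± 14.7 FPKM. Of 22 genes of the tricarboxylic acid cycle 14 fell, including Idh3a (109 ± 24.1 against 202 ± 14.9 FPKM) and Mdh1 (378 ± 66.5 against 665 ± 11.6 FPKM), with camera adjusted p = 1.6e-08, and adjusted p = 0.13 with an estimated correlation. Of the 13 mRNAs encoded in mitochondrial DNA 7 fell, and 8 when adjusted over the list alone, such as mt-Nd3 and mt-Co3, which fell by 0.54 and 0.40 on the log2 scale (camera adjusted p = 0.00012, and adjusted p = 0.29 with an estimated correlation). The value of mt-Atp6 was higher but did not pass, at 12292 ± 10313 against 4065 ± 411 FPKM (limma adjusted p = 0.16). That of mt-Nd2 was far under the other members, at 2.19 ± 1.43 against 3.73 ± 0.265 FPKM. The share of fragments from the mitochondrial chromosome was 31.4% ± 2.02 after LPS against 35.4% ± 1.92 in Control (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows). Of 21 sarcomere genes 8 fell, or 9 when adjusted over the list alone, and 1, Xirp1, rose (camera adjusted p = 0.00012, and adjusted p = 0.13 with an estimated correlation). Myh6, the main myosin heavy chain of the adult mouse heart, was 1990.4 ± 142 against 4446 ± 682 FPKM, and Myl2, the ventricular regulatory light chain, was 1895 ± 187 against 3554 ± 148 FPKM. In the calcium handling list 9 of 25 genes fell, or 10 when adjusted over the list alone, including Asph and Hrc of the sarcoplasmic reticulum, which fell by 1.74 and 1.52 (camera adjusted p = 0.00013, and adjusted p = 0.13 with an estimated correlation). Sri of that list rose. Of 22 potassium and sodium channel genes 12 fell, including Kcnip2 (4.98 ± 3.27 against 25.4 ± 4.48 FPKM) and Kcna5 (log2 fold change -1.64), with camera adjusted p = 1.1e-06, and adjusted p = 0.13 with an estimated correlation. Of 12 cardiomyocyte markers 8 fell (camera adjusted p = 1.9e-06, and adjusted p = 0.069 with an estimated correlation). Of 6 erythroid genes 3 fell, Hbb-bt, Hbb-bs and Hba-a1, with Hbb-bs at 168 ± 100.4 against 583 ± 58.3 FPKM (camera adjusted p = 0.00091, and adjusted p = 0.13 with an estimated correlation). The alpha and the beta haemoglobin genes are near-identical pairs, so the values of single members are uncertain.

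In the panel of genes fixed beforehand, Il6 (6.69 ± 4.68 against 0.0619 ± 0.0475 FPKM) and Tnf (1.04 ± 0.329 against 0.0786 ± 0.0738 FPKM) rose, as did Hmox1, haem oxygenase (89.5 ± 40.5 against 6.98 ± 1.48 FPKM), Pdk4 (log2 fold change 1.23) and the apoptosis gene Bax (0.76). Nppb, brain natriuretic peptide, fell to 25.6 ± 14.5 against 123 ± 42.0 FPKM. Outside the panel, Ankrd1, a cardiac stress gene, rose to 3984 ± 1083 against 332 ± 55.5 FPKM. Tlr4, the LPS receptor, was 5.30 ± 3.58 against 7.53 ± 0.828 FPKM (adjusted p = 0.23), Nppa was 307 ± 167 against 237 ± 109 FPKM (0.67) and Myh7, the beta-myosin heavy chain, had an adjusted p of 0.86. Cpt1b, Akt1 and Bcl2 also stayed short of the threshold (adjusted p = 0.64, 0.63 and 0.87). Il1b at 0.727 ± 0.372 FPKM against 0.406 ± 0.0759, and Nlrp3 at 0.545 ± 0.199 against 0.156 ± 0.0635, were under the limit for testing. By camera 11 lists passed upward and 8 downward of 38 tested, 0 lists passed with an estimated correlation and 30 passed by fry, which tests whether a list's genes move on balance in 1 direction. In 6 lists the median or mean and the camera direction differed in sign. Every Control library lay apart from every LPS library in 37.4% of genes, where chance gives 2.86%. The median gene rose by 0.16 on the log2 scale. When each library was divided by its median ratio, which removes that shift, 2145 genes rose and 2109 fell. The count of decreases leaves out genes that the LPS+XJDHT files do not list, of which 59 of 64 tested in Control and LPS alone fell, a direction set by how such genes came to be listed.

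**Figure D1:**
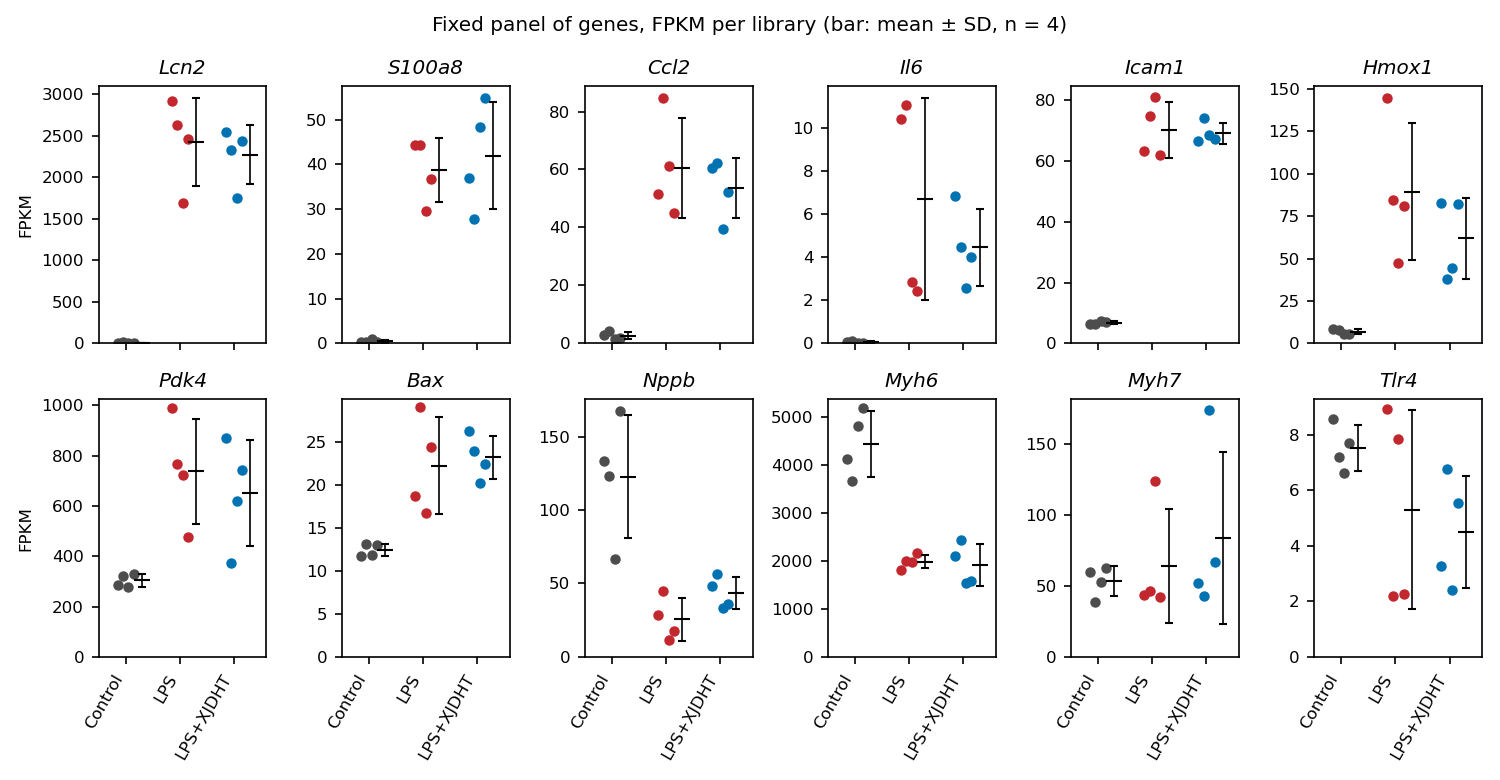
FPKM of 12 panel genes in each library, with points for the 4 libraries of a group and a bar for the mean ± SD. Lcn2, S100a8, Ccl2 and Icam1 are higher and Myh6 and Nppb lower in both LPS groups than in Control, and the LPS and LPS+XJDHT points overlap in all 12 genes.

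The comparison of LPS+XJDHT with LPS asks what the decoction changes in the heart of LPS-treated mice. The inflammatory and cardiac genes that LPS changed showed no difference that passed the test. Saa3 was 2526 ± 573 FPKM with XJDHT and 2681 ± 525 without it, and Lcn2 was 2270.5 ± 356 against 2425 ± 528 FPKM. Of 11509 genes 0 rose and 13 fell by limma, where 551 were under an unadjusted p of 0.05 and about 575 are due by chance. Every LPS+XJDHT library lay apart from every LPS library in 2.82% of genes, where chance gives 2.86%. Limma-voom called 0 up and 14 down, and limma with sample quality weights 3 up and 14 down. More genes passed without a filter and without mitochondrial and haemoglobin genes, as given in the section on processing. These counts leave out 283 genes listed for the LPS+XJDHT libraries alone, which by the way genes came to be listed can hold increases with XJDHT but hardly decreases.

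The 13 genes that fell are mostly expressed in other organs. Defa24, an alpha-defensin of the Paneth cells of the small intestine (chromosome 8, 21734494 to 21735471), was 0.126 ± 0.177 against 4.00 ± 0.984 FPKM (log2 fold change -2.14 ± 0.16, adjusted p = 0.00016). Fabp2, the intestinal fatty acid binding protein (chromosome 3, 122895072 to 122899506), was 0.0374 ± 0.0747 against 2.53 ± 0.710 FPKM (log2 fold change -1.75 ± 0.15, adjusted p = 0.00026). Defa20 and Defa2 fell by 1.86 and 1.65 on the log2 scale, with adjusted p = 0.00026 for each. Defa30 was 1.37 ± 0.0472 FPKM in LPS and listed at 0 in every LPS+XJDHT library. The other calls, named after their values were seen, were Defa32, Defa21, Gm7849 and Gm7861 of the same defensin cluster, Lyz1, the lysozyme of Paneth cells, Apoa1, an apolipoprotein of liver and intestine, Ldhc, the lactate dehydrogenase of testis, and Gm38394. Alpha-defensin genes are close paralogs that share reads, so the members are not separate observations. Gm38394, on chromosome 1 from 133619940 to 133661318, fell from 8.23 ± 2.46 to 0.904 ± 0.705 FPKM and belongs to a region where a Zc3h11a gene is listed for the LPS+XJDHT libraries alone. Of the 13, 0 reached the mean of 5 FPKM that the rule for named genes asks for in a gene that is not a predicted one. Summed over 26 measured genes of a small intestine list drawn up after the data were seen, 9 of them among the 13, FPKM was 48.8 ± 3.81 in LPS, 12.3 ± 2.38 in LPS+XJDHT and 7.40 ± 3.20 in Control. Without the genes of that list and of a similar testis list, 3 genes fell and 0 rose. With a limit of 5 FPKM for testing, 1 gene fell. Without LPS+XJDHT replicate 2, which had almost no RNA of Y-linked genes, 14 genes fell and 1 rose.

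The 5 genes with the smallest p among those higher with XJDHT did not pass. Supt20 was 3.56 ± 0.667 against 1.29 ± 0.516 FPKM (adjusted p = 0.064), Dus3l was 3.10 ± 1.23 against 0.924 ± 0.183 FPKM (0.074) and Mcf2l was 3.13 ± 1.13 against 0.554 ± 0.680 FPKM (0.15). Itga8 and Dact3 followed with adjusted p = 0.39 and 0.44. In some settings a call appeared: Mcf2l passed without LPS replicate 2, without LPS+XJDHT replicate 2 and with sample quality weights, with a smallest adjusted p of 0.013. Supt20 passed without LPS replicate 2 or 3, without a filter and with sample quality weights, and Dus3l without a filter and with a pseudocount of 0.1. In the panel, Nppb was 43.6 ± 10.7 against 25.6 ± 14.5 FPKM, Il6 4.46 ± 1.78 against 6.69 ± 4.68 FPKM, Tnf 0.613 ± 0.404 against 1.04 ± 0.329 FPKM and Hmox1 61.9 ± 24.1 against 89.5 ± 40.5 FPKM, each with an adjusted p of at least 0.99. Ccl2, Myh6, Bax, Bcl2, Tlr4 and Akt1 had log2 fold changes between -0.15 and 0.11.

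By camera 4 gene lists were lower with XJDHT than with LPS alone, 0 lists passed with an estimated correlation and 0 by fry. The count was 7 without LPS replicate 3 and 8 without LPS+XJDHT replicate 2. Most other splits of these libraries into 4 and 4 gave as many lists or more, as given in the last section, so the count does not exclude chance. Of 6 erythroid genes 0 passed over all genes and 5 fell when adjusted over the list alone, namely the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt and the haem synthesis gene Alas2 (camera adjusted p = 7.6e-06, and adjusted p = 0.29 with an estimated correlation). Hbb-bs was 84.6 ± 17.4 FPKM against 168 ± 100.4. Of 52 respiratory chain genes 0 passed over all genes or adjusted over the list alone, and their median log2 fold change was -0.06 (camera adjusted p = 4.2e-05, and adjusted p = 0.999 with an estimated correlation). Of 21 sarcomere genes 0 passed, with a median of -0.16 (camera adjusted p = 0.00032, and adjusted p = 0.42 with an estimated correlation). Of 23 cytokines and chemokines 0 passed over all genes and 1, Ccl5, fell when adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.42 with an estimated correlation). The sarcomere and the cytokine call were lost without LPS replicate 2, with adjusted p = 0.0502 and 0.16. Acute-phase, interferon-stimulated, TLR4 and NF-kB, neutrophil and ribosomal protein lists did not pass (camera adjusted p = 0.98, 0.053, 0.87, 0.98 and 0.98). In 7 lists the median or mean and the camera direction differed in sign.

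Whether genes changed by LPS moved back towards Control with XJDHT was counted directly. Of the 4447 genes that LPS changed, 11 passed in the opposite direction with XJDHT and 0 in the same direction. The opposite count was higher without a filter and without mitochondrial and haemoglobin genes, and 0 with a limit of 5 FPKM, as given in the section on processing. The 11 are the called genes other than Ldhc and Gm38394, and 9 of them are in the small intestine list. Since both comparisons share the LPS libraries, simulated data with no effect gave 0.0700 opposite calls on average and 7 at most, and independent lists would share 3.46. With the LPS libraries split 2 against 2 between the comparisons, 10 to 16 genes passed in opposite directions. Among the 865 genes that LPS raised at least 2-fold, with a median log2 fold change of 1.40, the median change with XJDHT was -0.06. Among the 393 that LPS lowered at least 2-fold, with a median of -1.28, it was 0.15. Across genes, which are not independent replicates, the 2 sets of fold changes had r = -0.28, and simulated data with no effect gave -0.44 on average (-0.92 to 0.59), which the LPS effect makes hard to compare. The covariance was -0.0589, where simulated data gave -0.0420 on average (-0.141 to 0.0190), a difference of -0.0168. With split LPS libraries r was between -0.15 and 0.15 and the covariance between -0.0384 and 0.0453. These values leave open whether genes in general moved towards Control.

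The comparison of LPS+XJDHT with Control asks how far hearts of treated mice differ from those of saline mice. The picture was close to that of LPS alone, with 3278 genes rising and 1234 falling, of which 867 and 350 changed at least 2-fold. Saa3 reached 2526 ± 573 against 3.17 ± 0.544 FPKM (log2 fold change 9.22 ± 0.19, adjusted p = 1.0e-10) and Lcn2 2270.5 ± 356 against 7.39 ± 3.64 FPKM (8.15 ± 0.26, adjusted p = 3.8e-09). Serpina3n and Cfb had log2 fold changes of 5.93 and 5.44, and Cxcl13 was between 24.8 and 52.0 FPKM with every Control library listed at 0. Ppp1r3c, H2-Eb1 and H2-Aa fell by 3.10, 2.97 and 2.89 on the log2 scale. Hba-a2, an alpha-globin gene, was 36.0 ± 27.4 against 250.1 ± 96.7 FPKM (log2 fold change -3.03 ± 0.62), and Hbb-bt, a beta-globin gene, was 33.9 ± 6.62 against 249 ± 67.4 FPKM (-2.82 ± 0.31). The panel genes Il6, Hmox1, Pdk4 and Bax rose, with log2 fold changes of 2.31, 2.91, 1.03 and 0.84, and Nppb fell by 1.43. Tnf rose by 0.55 (adjusted p = 0.030), a call lost without Control replicate 1, 3 or 4 and without LPS+XJDHT replicate 2 or 4, with adjusted p up to 0.072. Tlr4, Nppa and Myh7 did not pass (adjusted p = 0.17, 0.72 and 0.46).

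By camera 10 gene lists passed upward and 8 downward, 0 passed with an estimated correlation, 30 passed by fry, and in 4 lists the median or mean and the camera direction differed in sign. Of 33 interferon-stimulated genes 27 rose and 1 fell, or 28 rose when adjusted over the list alone (camera adjusted p = 1.2e-07, and adjusted p = 0.16 with an estimated correlation). Of 23 cytokines and chemokines 17 rose, or 18 when adjusted over the list alone, and 2, Ccl6 and Cxcl12, fell (camera adjusted p = 2.4e-05, and adjusted p = 0.061 with an estimated correlation). All 7 neutrophil markers rose (camera adjusted p = 2.0e-07, and adjusted p = 0.061 with an estimated correlation), as did 17 of 21 acute-phase and antibacterial genes, or 18 when adjusted over the list alone (camera adjusted p = 6.0e-13, and adjusted p = 0.061 with an estimated correlation). Of 35 ribosomal protein genes 32 rose, or 33 when adjusted over the list alone (camera adjusted p = 9.3e-14, and adjusted p = 0.13 with an estimated correlation). Of 52 respiratory chain genes 44 fell, or 47 when adjusted over the list alone, with Cox7a1 at 413 ± 27.4 against 739.6 ± 93.2 FPKM (camera adjusted p = 6.4e-23, and adjusted p = 0.061 with an estimated correlation). Of 21 sarcomere genes 10 fell, with Tnni3, cardiac troponin I, at 147 ± 45.7 against 745 ± 173 FPKM (camera adjusted p = 2.3e-07, and adjusted p = 0.061 with an estimated correlation). Of 12 cardiomyocyte markers 8 fell (camera adjusted p = 5.3e-07, and adjusted p = 0.061 with an estimated correlation), and of 6 erythroid genes 5 fell (camera adjusted p = 6.0e-06, and adjusted p = 0.064 with an estimated correlation). The monocyte list passed with camera adjusted p = 0.0495, and adjusted p = 0.27 with an estimated correlation, and lost its call without any of 7 libraries: Control replicate 2, each LPS replicate, and LPS+XJDHT replicates 3 and 4 (adjusted p up to 0.076). The mitochondrial share of fragments was 31.2% ± 1.52 against 35.4% ± 1.92 in Control (exact permutation test, two-sided, p = 0.0286).

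The changes against Control were largely shared with those of LPS alone. In both comparisons 2684 genes rose and 1031 fell, and 1 gene, Zfp408, passed in opposite directions. Independent lists would share 872 and 148, and simulated data with no effect shared 0. With the Control libraries split 2 against 2 between the comparisons, 1703 to 1798 genes rose and 592 to 654 fell in both. Across genes the 2 sets of fold changes had r = 0.92, against 0.78 to 0.80 with split Control libraries and 0.49 on average in simulated data with no effect, and their covariance was 0.459 against a simulated 0.0423. A further 731 genes passed after LPS alone and 796 after LPS+XJDHT alone, but the direct test of the difference between those groups called 13. Under scaling by median ratios 1966 genes rose and 2044 fell against Control, where the median gene had risen by 0.19 on the log2 scale. Every library of 1 group lay apart from the other in 42.1% of genes, where chance gives 2.86%. The p-values of single genes and of the mitochondrial share measure spread between libraries of separate mice. Camera p-values at the preset correlation of 0.01 compare the genes of a list with other genes and do not measure that spread.

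**Figure D2:**
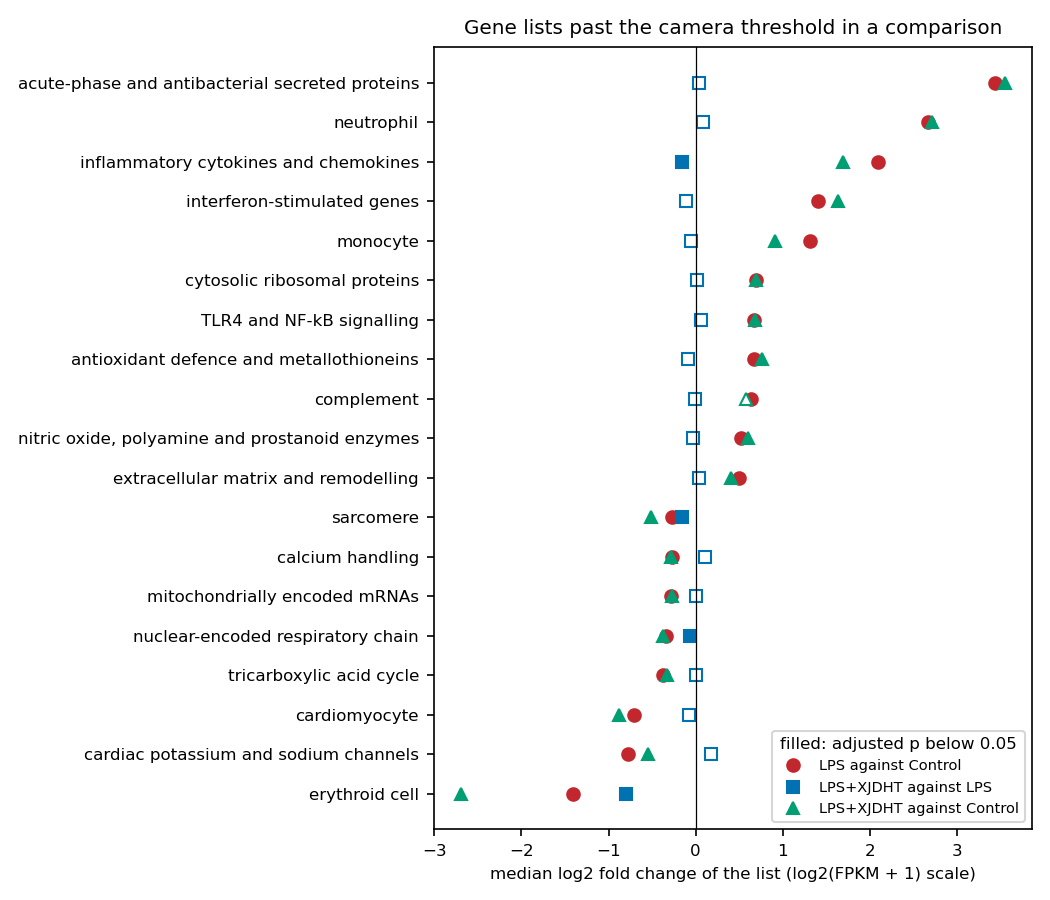
Median log2 fold change, on the log2(FPKM + 1) scale, of the 19 gene lists past the camera threshold in at least 1 comparison, with a marker for each comparison, filled where the adjusted p is below 0.05. Circles (LPS against Control) and triangles (LPS+XJDHT against Control) lie on the same side of 0 for every list shown, from -2.70 for erythroid genes to 3.55 for acute-phase genes, and squares (LPS+XJDHT against LPS) lie between -0.16 and 0.17 except for erythroid genes at -0.80.

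**Figure D3:**
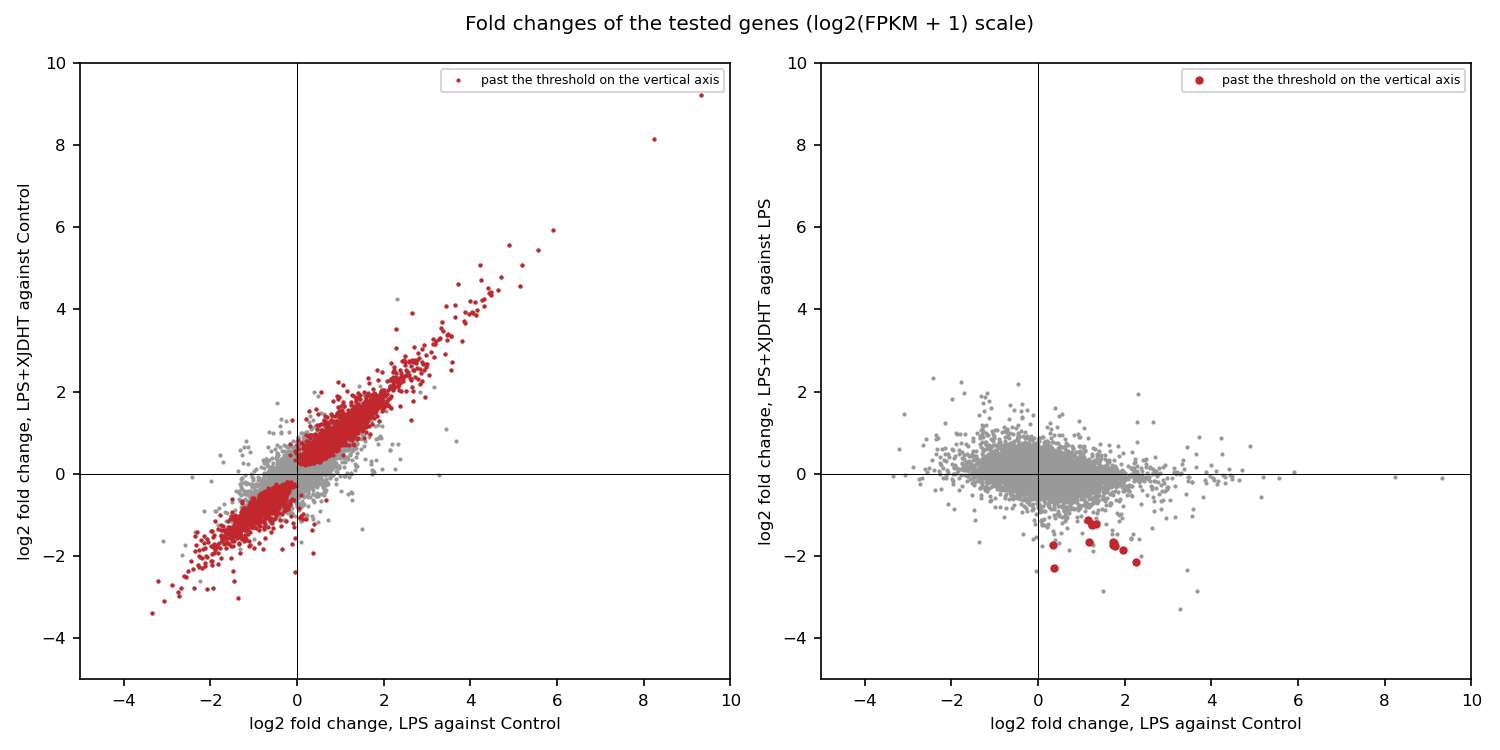
Log2 fold change of each tested gene after LPS (horizontal) against that of LPS+XJDHT relative to Control (left) or to LPS (right), on the log2(FPKM + 1) scale, with genes past the threshold on the vertical axis in red. On the left the points follow the diagonal (r = 0.92), and on the right 13 genes, all lower with XJDHT, pass. The panels share the Control or the LPS libraries between their axes, which alone tilts the clouds.

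**Figure D4:**
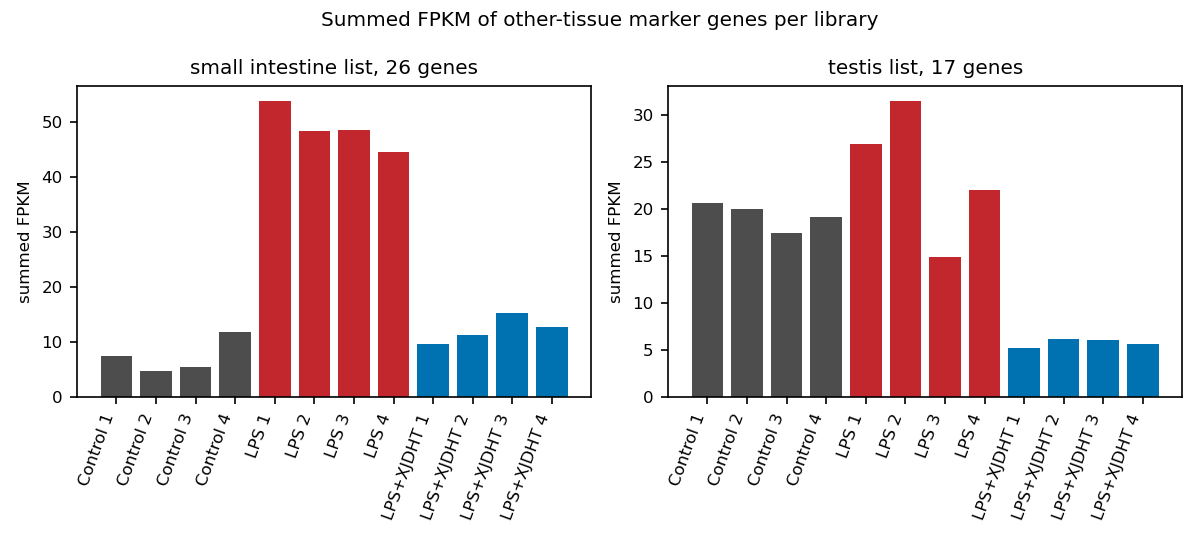
Summed FPKM of 26 small intestine genes (left) and 17 testis genes (right) in each library, as bars coloured by group. The small intestine sums lie between 44.5 and 53.8 in LPS and at or under 15.4 elsewhere, and the testis sums lie between 5.22 and 6.15 in LPS+XJDHT and at or above 14.9 elsewhere.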

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

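The small intestine and testis lists, the tests that use them, the tests of a swap and the comparisons of X-linked ratios and of single X-linked genes with other libraries were chosen after the results were seen.

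Small intestine genes stood out in the LPS libraries: 23 of 26 measured genes of the list lay higher in every LPS library than in every other library. Of the 17 that the test of LPS+XJDHT against LPS did not call, 14 did so, or 82.4%, where 0.400% of 6750 other genes with LPS means in the same range did. That 0.400% is no chance level for the list. A gene with hardly any RNA in the other groups is listed for all libraries only when its LPS mean reaches about 0.5 FPKM, which favours this pattern. The same limit holds for the genes named next. An LPS response of antibacterial genes that XJDHT prevents is argued against as the whole cause, since 6 genes without such a role, Apoa1, Fabp2, Krt20, Muc3, Tff3 and Vil1, showed the same pattern. Apoa1 and Fabp2 were among the called genes seen before the list was drawn up, so this rests on Krt20, Muc3, Tff3 and Vil1. RNA of small intestine in the LPS libraries may account for the pattern, with Reg3b at 5.37 FPKM and Defa24 at 4.00 the highest of the 23, although Cldn15, Lgals4 and Reg3a of the list did not follow it and the first 2 of these were above 1 FPKM in Control heart. Whether such RNA came from the mice, the dissection or the library preparation stays open, and group and batch cannot be told apart, since the labels give no batch.

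Testis genes showed another pattern: 6 genes were above 0 in all 8 Control and LPS libraries and at 0 in all 4 LPS+XJDHT libraries, and 4 of these, Prm1, Crisp2, Fabp9 and Ldhc, are in the testis list (66.7%). A difference in how the LPS+XJDHT files were quantified cannot be told apart from a difference in RNA on that share, since it rests on 6 genes and a list drawn up after some of them were seen, and since 1 Zc3h11a gene is listed in those files alone. Of the 13 other measured testis genes 100% were higher on average in Control and LPS than in LPS+XJDHT, where 40.9% of 5964 other genes in the same range were. These shares cannot be compared as a test, since a gene with hardly any RNA in heart is listed for all libraries mainly through its LPS mean. Listing acts alike on Control and LPS+XJDHT, where the sums over the 17 measured list genes were 19.3 ± 1.37 and 5.79 ± 0.441 FPKM. RNA of testis in the Control and LPS libraries is a candidate explanation, with Hspa1l at 5.02 FPKM and Meig1 at 2.30 the highest of the list in Control and 8 of the 19 list genes that the Control files hold at 1 FPKM or more there. No biological explanation was tested.

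LPS+XJDHT replicate 2 had a sum of 0.205 FPKM over 4 Y-linked genes, where the other 11 libraries had 20.4 to 61.9. A swap with a Control library is argued against, since this library lay at 20.2 on the leading component and the Control libraries between -54.0 and -49.1. A swap with an LPS library cannot be told apart: the small intestine sum was 11.4 here and at least 44.5 in LPS, but such RNA can come from handling, and no more than 3 genes outside the added lists passed between the 2 groups. Either swap would change the group of this library and not its lack of Y-linked RNA, which all other libraries hold. A female animal would lack RNA of Y-linked genes, but the X-linked genes used here leave it open. The median ratio of 3 X-linked genes that escape inactivation to the other LPS+XJDHT libraries was 1.29, where the highest ratio of any other library to its group was 1.16. The members were uneven, with Ddx3x at 1.51, Kdm5c at 1.29 and Eif2s3x at 0.990, Ddx3x was higher still in LPS 1 and LPS 2, which have RNA of Y-linked genes, and Xist and Kdm6a were not used here.

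In 33 of 361 groups of 4 libraries examined, 1 library lay far from the other 3 for a named gene, where chance gives about 5% and genes are not independent. The ranges that follow are those of the other 3 libraries of the group. In LPS+XJDHT 2, B2m was 795 FPKM against 1303 to 1374, Defa2 was 0.246 FPKM against 0, Defa20 was 0.339 FPKM against 0 and Eif2s3y was 0.199 FPKM against 11.9 to 14.4. In the same library Fabp2 was 0.149 FPKM against 0, Kdm5d was 0.00658 FPKM against 1.78 to 2.14, Mcf2l was 1.47 FPKM against 3.44 to 3.94 and Saa3 was 1668 FPKM against 2753 to 2858. In the same library Timp1 was 95.4 FPKM against 149 to 156 and Uty was 0 FPKM against at least 1.21. In LPS+XJDHT 1, Ndufb10 was 235 FPKM against 185 to 192 and Tnni3 was 80.3 FPKM against 155 to 177. In LPS+XJDHT 3, Cxcl1 was 23.5 FPKM against 38.6 to 41.7, Immp1l was 0 FPKM against 14.5 to 24.0 and Scn4b was 2.49 FPKM against 2.15 to 2.18. In LPS 1, Actc1 was 417 FPKM against 1117 to 1168, Adamts4 was 18.1 FPKM against 6.84 to 7.87, Ckm was 206 FPKM against 232 to 237 and Dact3 was 1.26 FPKM against 2.04 to 2.15. In the same library Hrc was 95.3 FPKM against 113 to 115. In LPS 3, Mmp3 was 78.4 FPKM against 109 to 109.9, Myh7 was 124 FPKM against 42.1 to 46.9, Ngp was 8.62 FPKM against 11.8 to 12.4 and S100a9 was 32.0 FPKM against 48.3 to 51.0. In Control 1, Cxcl5 was 0.216 FPKM against 0.155 to 0.164. In Control 2, Arg1 was 0.334 FPKM against 0, Cox7a1 was 878 FPKM against 676 to 706, Kcnip2 was 18.8 FPKM against 27.2 to 28.6 and Sele was 0.0183 FPKM against 0. In Control 3, Fabp2 was 0.0399 FPKM against 0 and Nppa was 78.3 FPKM against 261 to 327. In Control 4, Carnmt1 was 0.111 FPKM against 9.09 to 10.5 and Defa24 was 0.123 FPKM against 0.

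Data outside the comparisons also differed between groups. Of 6227 assembled transcripts without an Ensembl identifier, 1192 differed between LPS and Control by limma, 891 higher and 301 lower after LPS. Of 64 tested genes listed in the Control and LPS files alone, 59 were lower and 0 higher in LPS. That direction follows from the listing, since 5 of the 3156 transcripts absent from the LPS+XJDHT files had an LPS mean of 0.5 FPKM or more. A Zc3h11a gene on chromosome 1 that overlaps another gene of that name had a mean of 16.6 ± 1.21 FPKM in the LPS+XJDHT libraries and is not listed for the others.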

How the results depend on the processing

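The tests with median-ratio scaling, limma-voom, sample quality weights, all transcripts of 2 groups, and removal of small intestine and testis genes were chosen after the results were seen. For LPS against Control, 4043 of 4140 values of 167 named genes kept their direction and side of the threshold over the alternatives and 97 lost the threshold, for LPS+XJDHT against Control 3713 of 3831 and 118, and for LPS+XJDHT against LPS 664 of 675 and 2, with 9 passing newly. A change of sign past the threshold occurred in 0 of them. Leaving out each library in turn gave 3808 (without Control replicate 3) to 4618 genes for LPS against Control, 3720 (without LPS+XJDHT replicate 1) to 4805 for LPS+XJDHT against Control, and 13 to 19 for LPS+XJDHT against LPS, always including the 13 reported, with 11 to 16 moving back towards Control. The gene lists numbered 17 to 21, 16 to 21 and 3 to 8 in that order, with 3 for LPS+XJDHT against LPS without LPS replicate 2, 7 without LPS replicate 3 and 8 without LPS+XJDHT replicate 2.

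For LPS+XJDHT against LPS, no filter gave 43 genes (2 up, 41 down) and 34 moving back, and a limit of 5 FPKM gave 1 and 0. Apart from predicted genes, the called genes had means under 5 FPKM. Without mitochondrial and haemoglobin genes the counts were 21 and 17, with values rescaled and more genes past the filter, and without small intestine and testis genes 3 and 2, as those genes were removed. A minimum of 2-fold left 1258 genes for LPS against Control and 1217 for LPS+XJDHT against Control by construction. With an estimated correlation 0 gene lists passed in each of the 3 comparisons. By fry 30 passed in LPS against Control, 0 in LPS+XJDHT against LPS and 30 in LPS+XJDHT against Control, where the cause was not tested beyond fry asking another question. In LPS+XJDHT against Control the extracellular matrix list lost its call without Control or LPS+XJDHT replicate 3 (adjusted p up to 0.065). Alternatives planned for counts (relative log expression factors, DESeq2, voom and voom with weights on counts) were not run, as the files hold no counts. No paired analysis was possible because the numbers of the mice are not shared between groups. A listed 0 can be a failed estimate, and not only for genes under about 1 FPKM. Immp1l was listed at 0 in LPS+XJDHT 3, where the other libraries of the group had 14.5 to 24.0 FPKM. Carnmt1, listed at 0 in every LPS library, was at 0.111 FPKM in Control 4 against 9.09 to 10.5 in the other Control libraries.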

Other observations

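The tests of other splits were set before their results were seen, except that for genes moving back the labellings were counted as 70 afterwards and the splits with 2 libraries of each group were looked at afterwards, and the gene groups in the next paragraphs were fixed before the data were examined.

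Metabolic and clock genes moved in both directions after LPS. In the glycolysis list 7 of 25 genes rose and 8 fell: Pfkfb3, which makes the activator of phosphofructokinase, was 15.9 ± 1.48 against 2.57 ± 0.786 FPKM, while Eno3, the muscle enolase, was 199.7 ± 18.0 against 516 ± 37.7 FPKM and Ldhb fell by 0.79 on the log2 scale. In the fatty acid list 8 of 38 rose and 9 fell, with the transporter Cd36 at 626 ± 72.1 against 404 ± 31.8 FPKM, Acadm, the medium-chain acyl-CoA dehydrogenase, at 259 ± 38.6 against 389.8 ± 14.2 FPKM and the nuclear receptor Esrra falling by 1.23. Neither list passed as a whole (camera adjusted p = 0.21 and 0.11). Of 18 clock genes 4 passed: Dbp and Arntl fell by 1.19 and 1.00, and Per2 and Tef rose by 0.77 and 0.51 (camera adjusted p = 0.53). The labels give no time of day for the tissue. Eif4ebp1, a translational repressor in the PI3K-AKT list, rose by 1.75, and Tnfrsf1a, the main TNF receptor, by 1.57.

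Markers of resident cell types changed in part. Among 12 fibroblast markers 4 rose, including Pdgfra and Dcn with log2 fold changes of 1.40 and 1.11, and 3 fell, including Gsn. Among 12 pericyte and smooth muscle markers 3 fell, including Rgs5, by 1.04. Des of that list rose, at 612 ± 88.3 against 375 ± 40.8 FPKM, but heart muscle cells express it too. Of 13 macrophage markers 2 rose, Fcgr1 and Cd68, with log2 fold changes of 1.44 and 1.28. Of 12 endothelial markers 3 rose, including Cldn5 at 1.08. The camera adjusted p of these 4 lists was 0.87, 0.068, 0.71 and 0.36. In bulk tissue such values describe marker RNA and not cell numbers.

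Other splits of the 8 libraries of a comparison into 4 and 4 tested whether a grouping of mice by chance gives as much. For the counts of genes in the comparisons with Control chance can be excluded as far as 35 splits allow: the real split gave 4447 for LPS against Control and the highest other 2, so that 1 of 35 splits reached the real count. The same held for LPS+XJDHT against Control, with 4512 against 3 (1 of 35). The counts were 13 against 6 for LPS+XJDHT against LPS (1 of 35) and 11 against 4 for genes moving back towards Control (1 of 70 labellings). For these the splits cannot exclude chance, since genes were listed by the means of the real groups. Defa30, between 1.33 and 1.43 FPKM in the LPS libraries and at 0 in every LPS+XJDHT library, is listed through the LPS group alone. The 11 are among the 13, and most are small intestine genes, with defensin genes that share reads. The counts of 13 and 11 are thus not separate tests and do not show a return towards Control of other genes. For the gene lists by camera at the preset correlation the share of splits does not exclude chance. In LPS against Control 3 of 35 splits gave the real 19 lists or more, up to 23, in LPS+XJDHT against LPS 33 of 35 gave the real 4 or more, up to 21, and in LPS+XJDHT against Control 5 of 35 gave the real 18 or more, up to 23. In the comparisons with Control the other splits that reached the real count all kept 3 of 4 libraries of a group together and so part of the group difference, and those with 2 libraries of each group on either side gave at most 9 and 8 lists.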
